A study of Mus musculus with 14 samples.

How the data were processed

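PolyA-enriched RNA of mouse ventricles was sequenced in 14 libraries: 3 WT sham, 4 WT TAC, 3 Rad KO sham and 4 Rad KO TAC, grouped and numbered per the labels. The deposited data are 2 tables, each pairing TAC with sham within a genotype label, with 24279 genes in the WT table, 23925 in the Rad KO table and 22136 in both. The lowest total of a gene was 2 in each table, and the highest total among the 3932 genes in 1 table was 24. The authors deposited a count per gene and library, per the file headers. The deposited normalized signal of a library is its count over 1 factor, set within each table, as checked on the values. The deposited FPKM values are, per the file headers and a check on the values, the count over gene length and a constant of the library. The log2 fold change of TAC over sham and its p-value and adjusted p-value were deposited by the authors, per the file headers, for each table. HISAT2, DESeq2, edgeR and the build mm10 are named in the submitters' processing notes. Their versions, roles and order, the read counter, the annotation release and any filters are not given in the sources used here. Of the gene IDs, 99.9% were found in GENCODE M21 (GRCm38), 97.2% of these with the same coordinates, and 0 per-sample columns were left without a sample.

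The tests here used the deposited counts. Each TAC effect was fitted on the 7 libraries of its label with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr with a minimum count of 10 and a minimum total of 15, quasi-likelihood F-test), with Benjamini-Hochberg adjustment and a threshold of 0.05. The difference of the TAC effects and the Rad KO against WT contrasts came from 1 model of 4 groups and 14 libraries on the genes in both tables. The SE of a log2 fold change is its size over the square root of F. The SE of a list median comes from the spread over the genes of the list, taken as independent, and not from the libraries. CPM values are counts per 1000000 with TMM scaling over the 14 libraries. Gene lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01 and again with an estimated correlation, and with fry. Of 30 lists, 27 were tested, since the neutrophil, atrial and sex-linked lists had fewer than 3 tested members. Total counts per library were 14546176 to 23314792, with a count in 18884 to 20374 genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

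The named genes followed a rule: up to 8 per direction within a label with the largest change past the threshold, protein-coding, with a mean of at least 50 counts in the higher group and no overlap between TAC and sham libraries. In the other contrasts the rule named up to 6 per direction, or the 4 with the smallest p where 0 passed. It added Rrad, 12 fixed genes and up to 3 members per list and label. The comparisons, tests, lists, this rule and the alternatives were set before the data were examined, except where the text says otherwise. The exceptions are the alternatives without the sham libraries whose Esr1 level was unlike others of their label, the genes said to be named after their values were seen, and the tests and the condition on a verdict that the closing section says were chosen or added afterwards. The scripts were tested on simulated data drawn from the real means and dispersions, with each gene drawn independently and no library set apart. For 2-fold and 4-fold changes, recovery was 71.4% and 96.9% for TAC in WT (14137 genes), 72.4% and 96.9% in Rad KO (13924), 60.2% and 89.9% for Rad KO against WT in sham (14514), and 71.7% and 98% in TAC (14520).

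The alternatives were DESeq2 1.42.0, its size factors within edgeR, no filter on low counts, the replicate number as a block, a single model of 14 libraries, an absolute log2 fold change of at least 1, an adjusted p under 0.01, an estimated correlation for lists, other gene sets for the agreement of the TAC effects, and leaving out each library in turn. The planned pseudocounts and the count test on recovered reads did not apply, since the tables hold counts. Results for some genes that the rule would name are not reported here.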

Results

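Messenger RNA of mouse ventricles was measured by sequencing 14 polyA-enriched libraries. They fell into 4 groups by genotype label and operation: 3 WT sham, 4 WT TAC, 3 Rad knockout (Rad KO) sham and 4 Rad KO TAC. TAC is transverse aortic constriction, a surgical narrowing of the aortic arch that loads the left ventricle with pressure. A sham animal has the operation without the narrowing. Rad, encoded by Rrad, is a small GTPase of the RGK family that restrains the cardiac L-type calcium channel. The knockout was induced with tamoxifen, given 4 weeks after TAC, and tissue was taken more than 2 months after TAC and more than 1 month after the knockout. The design therefore asks what removing Rad does to a ventricle already under pressure load. Total counts per library ranged from 14546176 in Rad KO TAC 4 to 23314792 in WT sham 1. The other 12 libraries held between 14598526 and 17652010. The labels do not state that the libraries of a group came from separate animals, so the p-values measure the spread between these libraries. Levels are given as counts per 1000000 (CPM), as mean ± SD over the libraries of a group. Coordinates are those of the mm10 build in the deposited tables.

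The targeted gene was read in every library. Rrad (ENSMUSG00000031880, chromosome 8, 104628070 to 104631327, minus strand) had 213, 229 and 199.6 CPM in WT sham 1 to 3 and 128, 223, 242 and 208 CPM in WT TAC 1 to 4. The libraries labelled Rad KO had 162, 183 and 228 CPM in sham 1 to 3, and 164, 243, 198.6 and 119 CPM in TAC 1 to 4. Rrad in Rad KO against WT had a log2 fold change of -0.17 (SE 0.23) in sham and -0.14 (SE 0.20) in TAC, with adjusted p = 0.944 and 0.93 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, as for every adjusted p of a gene below). TAC against sham gave a log2 fold change of -0.09 (SE 0.19) in WT and -0.07 (SE 0.21) in Rad KO. The gene-level counts cover the whole gene and the deleted part is not given in the sources used here, so reads from undeleted exons would count in full. Because the Rrad difference did not pass the threshold, the groups are called libraries labelled Rad KO, and every direction drawn from that label rests on the label alone. Esr1, which encodes an oestrogen receptor, parted libraries of 1 label. It stood at 1.27, 1505 and 2226 CPM in WT sham 1 to 3, and at 2020.3, 1.12 and 1934.5 CPM in Rad KO sham 1 to 3. The 4 WT TAC libraries had 0.56 to 1.61 CPM of Esr1 and the 4 libraries labelled Rad KO TAC had 338.5 to 2463 CPM.

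**Figure D1:**
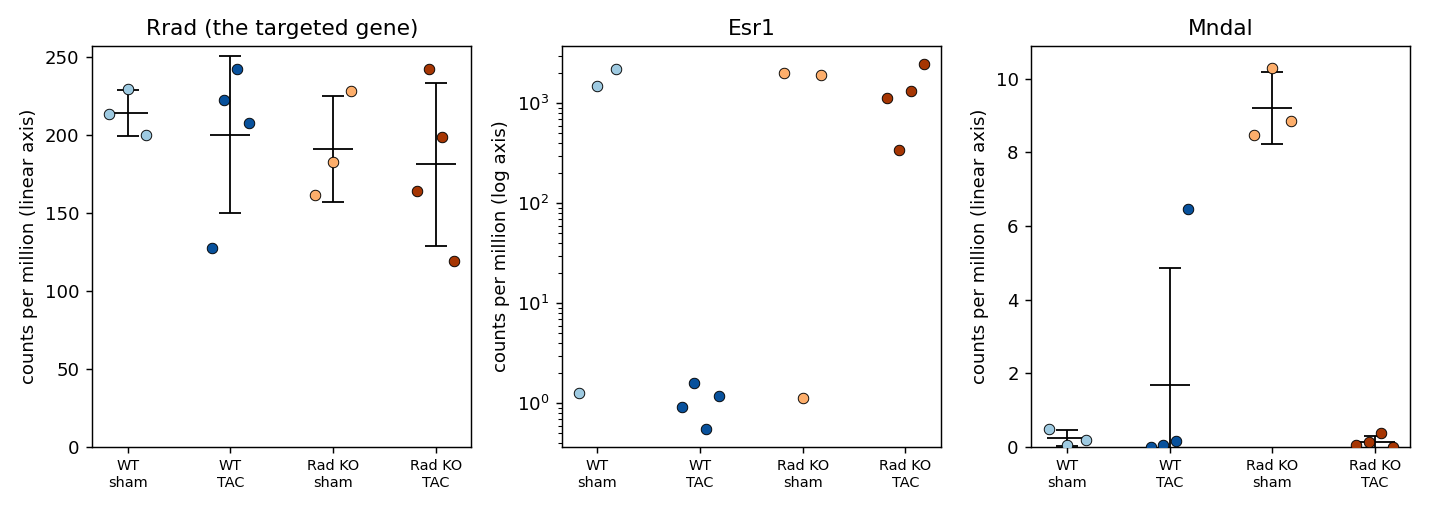
Each point is the level of Rrad, Esr1 or Mndal in a library, in CPM (linear axes for Rrad and Mndal, a log axis for Esr1), with bars at the group mean ± SD for Rrad and Mndal. Rrad means lay between 181 CPM in Rad KO TAC and 214 CPM in WT sham, Esr1 stood above 338 CPM in 8 libraries and at or under 1.61 CPM in the other 6, and Mndal stood above 6 CPM in the 3 Rad KO sham libraries and in WT TAC 4.

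The first comparison asks what TAC did in WT ventricles. After TAC, 9 of 12 load-responsive and 17 of 34 extracellular matrix genes rose, and 5 of 21 potassium, sodium and gap junction channel genes and 3 of 5 Schwann cell markers fell. These 4 lists were called by limma camera with the preset correlation, and had adjusted p = 0.0687, 0.179, 0.095 and 0.0619 with an estimated correlation. Nppb (ENSMUSG00000029019, chromosome 4, 147985788 to 147987205), which encodes B-type natriuretic peptide, rose from 87.5 ± 28.1 CPM in sham (n = 3) to 651 ± 392 CPM in TAC (n = 4), a log2 fold change of 2.89 (SE 0.47). Myh7 (ENSMUSG00000053093, chromosome 14, 54970684 to 54994626), the slow beta-myosin heavy chain, rose from 170.4 ± 15.2 to 3197 ± 2553 CPM (1961 CPM without WT TAC 3), a log2 fold change of 4.23 (SE 0.56). Cenpf (ENSMUSG00000026605, chromosome 1, 189640606 to 189688086), a kinetochore-associated protein, fell from 54.3 ± 12.2 to 7.07 ± 2.66 CPM, a log2 fold change of -2.94 (SE 0.26). Their adjusted p by edgeR's quasi-likelihood test were 0.0143, 0.00838 and 0.00149. The size of the Cenpf fall cannot be parted from the Esr1 level, as set out below. Of 14323 genes tested, 287 rose and 155 fell, and 2486 had an unadjusted p under 0.05 where 716 would by chance.

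The protein-coding genes with the largest rises in WT began with Lrp8, a lipoprotein receptor that also binds reelin, with a log2 fold change of 5.11 (SE 0.81) from 0.188 CPM in sham to 6.86 CPM in TAC. Serpinb1c, a member of a serine protease inhibitor family with close copies that can share its reads, had 4.58 (SE 0.89). Lman1l, related to a cargo receptor of the secretory pathway, had 4.33 (SE 0.49). Nppa, the atrial natriuretic peptide gene, had 3.97 (SE 0.63), from 52.3 ± 15.6 to 817 ± 668 CPM. The T-box transcription factor Tbx15 had 3.89 (SE 0.32), and the chitinase-like glycoprotein gene Chil1 had 3.75 (SE 0.87). The largest falls were led by Cacng6, a gamma subunit of calcium channels, at -3.08 (SE 0.47), from 4.86 ± 0.215 to 0.585 ± 0.435 CPM. After Cenpf came the water channel Aqp4 at -2.78 (SE 0.58), Tmem56 at -2.47 (SE 0.32) and Tbc1d10c, an inhibitor of calcineurin, at -2.37 (SE 0.35). Acta2, the smooth muscle actin, fell by 2.14 on the log2 scale (SE 0.42), with 158, 609.5 and 675 CPM in WT sham 1 to 3 and 72.7 to 156 CPM in WT TAC, so that WT sham 1 stood at the level of WT TAC 1 (156 CPM). Acta2 lost its call without WT sham 2 (-1.93), WT sham 3 (-1.81), WT TAC 2 (-2.19), WT TAC 3 (-1.99) or WT TAC 4 (-2.04), with edgeR quasi-likelihood adjusted p from 0.0528 to 0.141, and had -0.53 (0.954) without both WT sham 2 and 3. The mitochondrial folate enzyme Aldh1l2 fell by 2.05 (SE 0.27), and Ano10, of the anoctamin family, fell by 1.99 (SE 0.29). With Myh7 and Cenpf, these 15 genes had adjusted p between 0.00149 for Tbx15 and Cenpf and 0.0485 for Chil1 by edgeR's quasi-likelihood test. Cenpf, Aqp4, Tmem56, Tbc1d10c, Aldh1l2 and Ano10 were lower in WT sham 1 (low Esr1) than in WT sham 2 and 3 (high Esr1). In WT sham 1 to 3, Cenpf stood at 40.3, 62.0 and 60.7 CPM, Aqp4 at 5.38, 13.5 and 12.9 CPM and Ano10 at 50.7, 123 and 135 CPM. The WT TAC libraries had low Esr1 as well and lay below WT sham 1 for these genes. The size of these falls therefore cannot be parted from the Esr1 level. Rad KO sham 2 (low Esr1) was likewise the lowest Rad KO sham library for each of these genes. Cenpf stood at 57.0, 14.6 and 28.8 CPM in Rad KO sham 1 to 3.

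Of the 12 load-responsive cardiomyocyte genes, 9 rose in WT when adjusted over all genes and 12 when adjusted over the list alone, with a median log2 fold change of 2.04. The list stood above other genes by limma's camera (adjusted p = 4.15e-28), with adjusted p = 0.0687 with an estimated correlation. Ankrd1, a stretch-responsive titin-binding repressor, rose from 981 ± 312 to 5141 ± 1841 CPM (log2 fold change 2.39, SE 0.31). Xirp2, an actin-binding protein of the intercalated disc, rose from 468 ± 71.0 to 1831 ± 508 CPM (1.97, SE 0.22). Acta1, the skeletal actin, had 833 ± 566 and 3570 ± 1939 CPM and did not pass (2.10, SE 0.59, edgeR quasi-likelihood adjusted p = 0.0932). Of 17 sarcomere genes 2 rose, 5 when adjusted over the list alone: Csrp3, a Z-disc LIM protein, at 0.59 (SE 0.13) and Actn2, the Z-disc alpha-actinin, at 0.48 (SE 0.11). The list's median was 0.14 (limma camera adjusted p = 0.00861, and adjusted p = 0.637 with an estimated correlation), and Myh6, the fast alpha-myosin heavy chain, whose sequence is close to that of Myh7, had -0.20 (SE 0.24).

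Of 34 extracellular matrix genes, 17 rose and 0 fell in WT, and 29 rose when adjusted over the list alone, with a median log2 fold change of 1.18. Camera placed the list above other genes (adjusted p = 3.47e-34), with adjusted p = 0.179 with an estimated correlation. Postn (ENSMUSG00000027750, chromosome 3, 54361109 to 54391037), the matricellular protein periostin, rose from 56.5 ± 27.4 to 314 ± 173 CPM (2.48, SE 0.49). Elastin, Eln, rose from 23.2 ± 3.11 to 95.2 ± 28.2 CPM (2.04, SE 0.21). Thrombospondin Thbs4 rose from 8.22 ± 2.24 to 54.3 ± 20.7 CPM (2.74, SE 0.31). Fibromodulin, Fmod, rose from 3.73 ± 1.89 to 31.9 ± 13.8 CPM (3.10, SE 0.43). The fibrillar collagen genes Col1a1, at 0.81 (SE 0.22), and Col3a1, at 0.57 (SE 0.27), did not pass, with adjusted p = 0.083 and 0.312 by edgeR's quasi-likelihood test. Col5a2, another fibrillar collagen gene, rose by 1.31 (SE 0.26). Of 17 TGF-beta and CCN genes, 11 rose, 16 when adjusted over the list alone, with a median of 1.24 (limma camera adjusted p = 3.04e-22, and adjusted p = 0.0687 with an estimated correlation). Among them Wisp2, a secreted CCN protein, rose from 4.58 ± 2.07 to 39.8 ± 22.8 CPM (3.13, SE 0.50). Cyr61, another CCN protein, rose by 0.86 (SE 0.14), and the homeobox gene Meox1 rose by 1.72 (SE 0.23). Of 13 immediate early genes 2 rose, 5 when adjusted over the list alone: Egr3, a zinc-finger factor, by 1.48 (SE 0.32) and Btg2, an antiproliferative gene, by 1.02 (SE 0.22). That list's median was 0.69 (limma camera adjusted p = 6.38e-05, and adjusted p = 0.583 with an estimated correlation).

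Of 21 potassium, sodium and gap junction channel genes, 5 fell and 0 rose in WT, and 8 fell when adjusted over the list alone, with a median of -0.38 (limma camera adjusted p = 1.34e-07, and adjusted p = 0.095 with an estimated correlation). Kcnip2 (ENSMUSG00000025221, chromosome 19, 45791839 to 45816061), the subunit of the transient outward potassium channel, fell from 289.6 ± 52.1 to 141 ± 27.8 CPM (-1.03, SE 0.17). Kcnj2, of the inward rectifier, fell from 76.3 ± 6.09 to 39.1 ± 6.84 CPM (-0.96, SE 0.14). Kcnh2, of the rapid delayed rectifier, fell from 137 ± 5.39 to 90.6 ± 10.8 CPM (-0.60, SE 0.11). Kcnip2 stood at 230, 327 and 312 CPM in WT sham 1 to 3, and Kcnj2 at 69.7, 81.7 and 77.5 CPM. Both were lowest in WT sham 1, with low Esr1, so the size of their falls cannot be parted from the Esr1 level. Kcnh2 did not follow Esr1 there, at 139, 131 and 142 CPM. Of 14 voltage-gated calcium channel and RGK genes, Cacnb1, a beta subunit, rose (1.04, SE 0.22) and Cacng6 fell, and Cacna1c, the pore of the L-type channel, had 0.00 (SE 0.14), with the same counts when adjusted over the list alone. That list's median was -0.07 (limma camera adjusted p = 0.542). Of 17 calcium handling genes 0 passed, adjusted over all genes or adjusted over the list alone, with a list median of -0.01 (limma camera adjusted p = 0.794), and the pump gene Atp2a2 had -0.30 (SE 0.16) and its inhibitor Pln -0.06 (SE 0.15). Of 19 beta-adrenergic signalling genes 0 passed, 4 fell when adjusted over the list alone, and the median was -0.13 (limma camera adjusted p = 0.0429, and adjusted p = 0.48 with an estimated correlation).

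In the WT energy lists, of 26 fatty acid oxidation genes, Etfb, a subunit of the electron transfer flavoprotein, fell from 69.7 ± 4.39 to 43.3 ± 8.04 CPM (-0.69, SE 0.14). There 1 gene passed also when adjusted over the list alone, and the median was -0.20 (limma camera adjusted p = 0.00239, and adjusted p = 0.752 with an estimated correlation). The 17 tricarboxylic acid cycle genes and the 27 nuclear oxidative phosphorylation genes each had 0 genes past the threshold, adjusted over all genes or adjusted over the list alone, and a median of -0.17. Their limma camera adjusted p were 0.00432 and 0.000645, with adjusted p = 0.752 for both with an estimated correlation. Of the 13 mitochondrially encoded genes, mt-Nd4l, a complex I subunit, fell from 476 ± 126 to 167 ± 54.8 CPM (-1.51, SE 0.24), and 1 gene passed when adjusted over the list alone. The list's median was -0.15 (limma camera adjusted p = 0.0333, and adjusted p = 0.752 with an estimated correlation), and the share of counts on mitochondrial genes was 21.7% ± 1.4 in WT sham and 19.4% ± 1.3 in WT TAC. Of 21 glycolysis and glucose uptake genes, Pfkp, a phosphofructokinase, rose (1.11, SE 0.20), 3 rose and 1 fell when adjusted over the list alone, and the list did not stand apart (median 0.05, camera adjusted p = 0.62).

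Lists that mark other cell types and states were read in the same WT comparison. Of 5 Schwann cell markers 3 fell, 4 when adjusted over the list alone, among them Gfra3, a neurotrophic factor receptor, by -1.85 (SE 0.32) and the transcription factor Sox10 by -1.63 (SE 0.37). That list's limma camera adjusted p was 1.34e-07, with adjusted p = 0.0619 with an estimated correlation. Of 11 fibroblast markers 2 rose, Mfap5, a microfibril protein (1.61, SE 0.34), and Pi16, a peptidase inhibitor (1.42, SE 0.26), also 2 when adjusted over the list alone, with a list median of 0.04 (limma camera adjusted p = 0.178). Of 12 mural cell markers, Acta2 fell and Des, the intermediate filament of cardiac as well as smooth muscle, rose (0.92, SE 0.13), 1 rose and 2 fell when adjusted over the list alone, with a median of -0.13 (limma camera adjusted p = 0.471). Of 3 adipocyte markers tested, Cidea, a lipid droplet protein, rose (0.67, SE 0.14), also when adjusted over the list alone, with a median of 0.67 (limma camera adjusted p = 0.324). The lists with 0 members past the threshold, adjusted over all genes or adjusted over the list alone, were those of macrophages (19 tested, median 0.12), lymphocytes (5, 0.22), endothelium (14, 0.00), erythrocytes (6, 0.18), epicardium and mesothelium (5, -0.49), cell cycle (14, -0.20), interferon-stimulated genes (13, -0.16), the unfolded protein response and oxidative stress (18, 0.08) and the circadian clock (14, -0.06). Their limma camera adjusted p ran from 0.165 for the interferon-stimulated genes to 0.794. Too few neutrophil markers (2), atrial markers (2) and sex-linked genes (1) were tested for a list test, and 0 of them passed, with medians of 0.58, -0.42 and -0.45.

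Each of the 442 calls in WT was also past an adjusted p of 0.05 in the authors' deposited table, which held 910 such genes, 588 higher and 322 lower, and DESeq2 run here called 933. The count fell to 15 without WT sham 3, 91 without WT sham 2, 243 without WT sham 1, 234 without WT TAC 2 and 276 without WT TAC 3. Without WT sham 2 and 3, the sham libraries with high Esr1, a single sham library was left and edgeR called 0 genes, with 947 at an unadjusted p under 0.05. Nppb lost its call without WT sham 2 (log2 fold change 2.72, edgeR quasi-likelihood adjusted p = 0.0654) or WT sham 3 (2.81, 0.0948), and Myh7 without WT sham 3 (4.25, 0.0679).

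**Figure D2:**
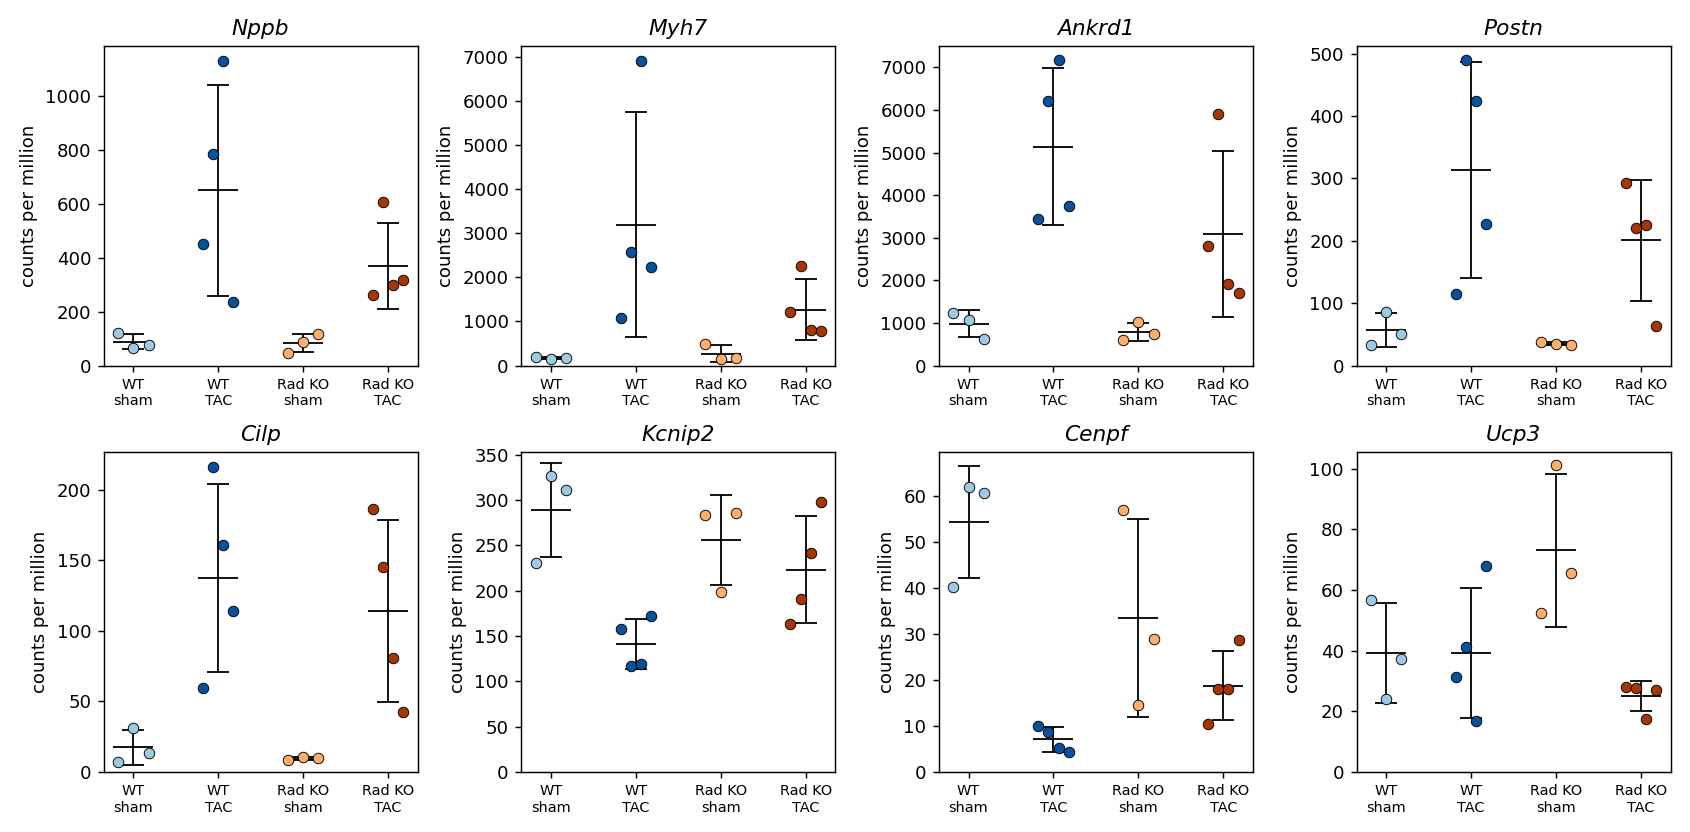
Each point is the level of a gene in a library, in CPM on a linear axis, with bars at the group mean ± SD (n = 3 sham and 4 TAC libraries per genotype label). Nppb averaged 651 CPM in WT TAC and 370 CPM in Rad KO TAC, and Ucp3 averaged 39.2 CPM in WT TAC and 25.0 CPM in Rad KO TAC against 73.0 CPM in Rad KO sham.

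The second comparison asks what TAC did in the libraries labelled Rad KO. After TAC, 19 of 34 extracellular matrix genes rose, and 2 of 26 fatty acid oxidation genes and 2 of 13 mitochondrially encoded genes fell. These 3 lists were called by limma camera with the preset correlation, and had adjusted p = 0.144, 0.273 and 0.193 with an estimated correlation. Comp (ENSMUSG00000031849, chromosome 8, 70373558 to 70382066), a matrix protein of cartilage and tendon, rose from 2.66 ± 0.439 CPM in sham (n = 3) to 72.9 ± 59.6 CPM in TAC (n = 4), a log2 fold change of 4.78 (SE 0.85). Nppb rose from 83.2 ± 34.1 to 369.8 ± 159 CPM (2.15, SE 0.34). Ucp3 (ENSMUSG00000032942, chromosome 7, 100472990 to 100486432), a mitochondrial uncoupling protein of muscle, fell from 73.0 ± 25.3 to 25.0 ± 5.05 CPM (-1.54, SE 0.22). Their adjusted p by edgeR's quasi-likelihood test were 0.0248, 0.0185 and 0.0152. Of 14122 genes tested, 148 rose and 91 fell, and 2450 had an unadjusted p under 0.05 where 706 would by chance.

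The largest rises after Comp were those of Gm11361, a predicted protein-coding gene, at 4.25 (SE 0.83), and Ltbp2, a binding protein of latent TGF-beta, at 4.16 (SE 0.69). Gm11361 was also low in single TAC libraries of either label, at 2.76 CPM in WT TAC 1 and 2.35 CPM in Rad KO TAC 2. Vgll2, a transcription cofactor of skeletal muscle, rose from 0.677 ± 0.0720 to 11.1 ± 7.93 CPM (4.02, SE 0.63), and the short-chain collagen gene Col8a2 rose by 3.66 (SE 0.67). Cilp, a cartilage matrix protein, rose from 9.40 ± 1.09 to 114 ± 64.6 CPM (3.60, SE 0.46), and Nlrc3, a NOD-like receptor family gene, rose by 3.51 (SE 0.59). The largest fall was that of Mndal (ENSMUSG00000090272, chromosome 1, 173849126 to 173942491), an interferon-inducible gene of a family with close copies, from 9.22 ± 0.992 to 0.140 ± 0.159 CPM (-5.92, SE 0.45). Its neighbour Ifi205, of the same family, had -3.83 (SE 0.42). Mndal stood at 6.46 CPM in WT TAC 4 and at no more than 0.481 CPM in the other WT libraries. Ano5, an anoctamin of skeletal muscle, had -2.67 (SE 0.44) and Abca4, a retinoid transporter, -2.13 (SE 0.37). The potassium channel gene Kcna2 had -1.98 (SE 0.38) and Pfkfb1, a regulator of glycolysis, -1.83 (SE 0.32). These 13 genes, Comp included, had adjusted p from 0.00112 for Mndal to 0.0362 for Gm11361 by edgeR's quasi-likelihood test.

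Of the 34 extracellular matrix genes, 19 rose and 0 fell in the libraries labelled Rad KO, and 29 rose when adjusted over the list alone, with a median of 1.30. Camera placed the list above other genes (adjusted p = 2.55e-39), with adjusted p = 0.144 with an estimated correlation. Postn rose from 35.1 ± 2.08 to 200.5 ± 97.7 CPM (2.52, SE 0.41). The thrombospondin gene Thbs1 rose from 4.58 ± 1.00 to 20.9 ± 6.88 CPM (2.20, SE 0.27) and Col8a1, a short-chain collagen, from 26.6 ± 2.08 to 65.1 ± 15.3 CPM (1.30, SE 0.17). Col1a1 and Col3a1 had 1.02 (SE 0.23) and 0.95 (SE 0.27) and did not pass, with adjusted p = 0.0616 and 0.109 by edgeR's quasi-likelihood test. Of 17 TGF-beta and CCN genes, 4 rose, 11 when adjusted over the list alone, with a median of 0.97 (limma camera adjusted p = 1.83e-10, and adjusted p = 0.144 with an estimated correlation). The 4 were Ctgf, a CCN protein, Wisp2 (3.42, SE 0.63), the activin subunit gene Inhba (1.45, SE 0.28) and Fstl1, a follistatin-like protein (1.05, SE 0.17).

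Of the 12 load-responsive cardiomyocyte genes, 2 rose in the libraries labelled Rad KO, Nppb and Ankrd1, and 12 rose when adjusted over the list alone, with a median of 1.15 (limma camera adjusted p = 2.3e-14, and adjusted p = 0.156 with an estimated correlation). Ankrd1 went from 791 ± 218 to 3082 ± 1948 CPM (1.97, SE 0.41). Nppa had 43.1 ± 24.3 and 501 ± 568 CPM (3.54, SE 0.77, edgeR quasi-likelihood adjusted p = 0.0519), with 1350 CPM in Rad KO TAC 2 and 148 to 262 CPM in the other TAC libraries of that label. Myh7 had 265.6 ± 195.6 and 1269 ± 689.5 CPM (2.26, SE 0.50, edgeR quasi-likelihood adjusted p = 0.0537). Rad KO sham 1 had 491 CPM of Myh7 against 142 and 163 CPM in sham 2 and 3, and without it the log2 fold change was 3.05 (edgeR quasi-likelihood adjusted p = 0.0591). Without Rad KO TAC 4, Myh7 passed (2.43, edgeR quasi-likelihood adjusted p = 0.0308). Of 12 immediate early genes, Nr4a1, a nuclear receptor, rose (1.20, SE 0.22), 6 rose when adjusted over the list alone, and the median was 0.60 (limma camera adjusted p = 3.91e-06, and adjusted p = 0.198 with an estimated correlation). The 17 sarcomere genes had 0 past the threshold, 2 higher and 1 lower when adjusted over the list alone, and a median of -0.05 (limma camera adjusted p = 0.664). Their list test pointed up while the median was negative.

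Of 26 fatty acid oxidation genes, 2 fell in the libraries labelled Rad KO, Ucp3 and Hadh, a beta-oxidation dehydrogenase (-0.51, SE 0.11), and 15 fell when adjusted over the list alone. The list's median was -0.39 (limma camera adjusted p = 3.01e-12, and adjusted p = 0.273 with an estimated correlation). Of the 13 mitochondrially encoded genes, mt-Atp6, an ATP synthase subunit, fell from 2053 ± 366 to 1132 ± 215 CPM (-0.85, SE 0.17) and mt-Nd5, a complex I subunit, fell (-0.62, SE 0.13), and 7 fell when adjusted over the list alone. That list's median was -0.46 (limma camera adjusted p = 5.95e-09, and adjusted p = 0.193 with an estimated correlation), and the share of counts on mitochondrial genes was 25.6% ± 2.4 in Rad KO sham and 21% ± 0.8 in Rad KO TAC. The tricarboxylic acid cycle list (17 tested, median -0.17) and the nuclear oxidative phosphorylation list (27 tested, median -0.13) had 0 genes past the threshold, adjusted over all genes or adjusted over the list alone. Their limma camera adjusted p were 0.00144 and 0.0122, with adjusted p = 0.464 and 0.591 with an estimated correlation. Of 21 glycolysis and glucose uptake genes, the enolase gene Eno1 rose (0.67, SE 0.13), 3 rose and 1 fell when adjusted over the list alone, and the median was 0.17 (limma camera adjusted p = 0.161).

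Of 21 potassium, sodium and gap junction channel genes, Kcnj11, the pore of the ATP-sensitive potassium channel, fell from 157 ± 19.2 to 105 ± 11.7 CPM (-0.57, SE 0.11), and 9 fell and 1 rose when adjusted over the list alone. The list's median was -0.36 (limma camera adjusted p = 3.84e-06, and adjusted p = 0.144 with an estimated correlation), and Kcnip2 had -0.19 with an edgeR quasi-likelihood adjusted p of 0.67. Kcnip2 stood at 284, 199 and 286 CPM in Rad KO sham 1 to 3, lowest in sham 2, with low Esr1. Every Rad KO TAC library had high Esr1, so this value cannot be parted from the Esr1 level either. Of 17 calcium handling genes, Ryr2, the sarcoplasmic calcium release channel, fell from 1873 ± 176 to 1221 ± 68.2 CPM (-0.61, SE 0.11), 2 fell when adjusted over the list alone, and the median was -0.09 (limma camera adjusted p = 0.117). The 14 voltage-gated calcium channel and RGK genes had 0 past the threshold and a median of -0.23 (limma camera adjusted p = 0.161), with Cacna1c at -0.33 (SE 0.12) and the auxiliary subunit gene Cacna2d1 at -0.38 (SE 0.11). Of 19 beta-adrenergic signalling genes, Adra1a, an alpha-adrenergic receptor, fell from 41.4 ± 10.1 to 19.8 ± 5.15 CPM (-1.05, SE 0.22), 3 fell and 2 rose when adjusted over the list alone, and the median was -0.21 (limma camera adjusted p = 0.0252, and adjusted p = 0.273 with an estimated correlation).

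Among lists for other cell types and states in the libraries labelled Rad KO, Mfap5 (1.31, SE 0.21) and Pi16 (1.49, SE 0.27) rose of 11 fibroblast markers, 3 when adjusted over the list alone, with a median of 0.34 (limma camera adjusted p = 0.0259, and adjusted p = 0.506 with an estimated correlation). The 14 cell cycle genes had 0 past the threshold and a median of 0.84, with 14 of 14 positive (limma camera adjusted p = 0.00011, and adjusted p = 0.144 with an estimated correlation). The highest of them was Birc5, a mitotic survivin gene, at 0.328 ± 0.264 and 0.949 ± 0.245 CPM (1.55, SE 0.57). The 13 interferon-stimulated genes had 0 past the threshold and a median of 0.44, with 13 of 13 positive (limma camera adjusted p = 0.0122, and adjusted p = 0.506 with an estimated correlation). The 5 Schwann cell markers had 0 past the threshold and a median of -0.81 (limma camera adjusted p = 0.00646, and adjusted p = 0.42 with an estimated correlation). The remaining tested lists had 0 members past the threshold, adjusted over all genes or adjusted over the list alone: macrophages (median 0.30), lymphocytes (0.34), endothelium (-0.14), mural cells (-0.30), adipocytes (-0.82), erythrocytes (0.37), epicardium and mesothelium (0.90), the unfolded protein response and oxidative stress (0.13) and the circadian clock (-0.06). Their limma camera adjusted p ran from 0.0541 for the epicardial and mesothelial list to 0.664 for the erythrocyte list. The neutrophil, atrial and sex-linked lists, too short for a list test, had medians of 0.97, -0.03 and -0.75 with 0 members past the threshold.

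Each of the 239 calls was also past an adjusted p of 0.05 in the authors' deposited table, which held 721 such genes, 438 higher and 283 lower, and DESeq2 run here called 753. The count was 11, 9 and 42 without Rad KO sham 1, 2 or 3, 150, 115 and 536 without Rad KO TAC 1, 3 or 4. Rad KO sham 2 was the sham library of that label with low Esr1. Comp lost its call without Rad KO sham 1 (log2 fold change 4.66), sham 2 (4.75) or sham 3 (4.90), Nppb without sham 1 (1.87) or sham 2 (2.17), and Ucp3 without sham 2 (-1.24), with edgeR quasi-likelihood adjusted p from 0.0678 for Ucp3 to 0.129 for Comp.

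Across the 13953 genes tested under both labels, the log2 fold changes of TAC in WT and in the libraries labelled Rad KO correlated with Pearson's r = 0.57 and Spearman's rho = 0.49. This is a correlation across genes, which are not independent replicates, and the 2 effects share no library. Among these genes, 66 rose under both labels where 3 would in independent lists, 9 fell under both where 1 would, and 0 went in opposite directions. Ctgf rose by 2.52 (SE 0.44) and 2.76 (SE 0.55), Postn by 2.48 and 2.52, and Lman1l by 4.33 and 3.41 (SE 0.71). Kcna2 fell by 1.40 (SE 0.29) in WT and by 1.98 in the libraries labelled Rad KO. Of the 434 WT calls tested under both labels, 410 had the same sign in Rad KO, and of the 234 Rad KO calls, 224 had the same sign in WT. The correlation was 0.74 over the genes called under either label and 0.21 without the filter on low counts.

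**Figure D3:**
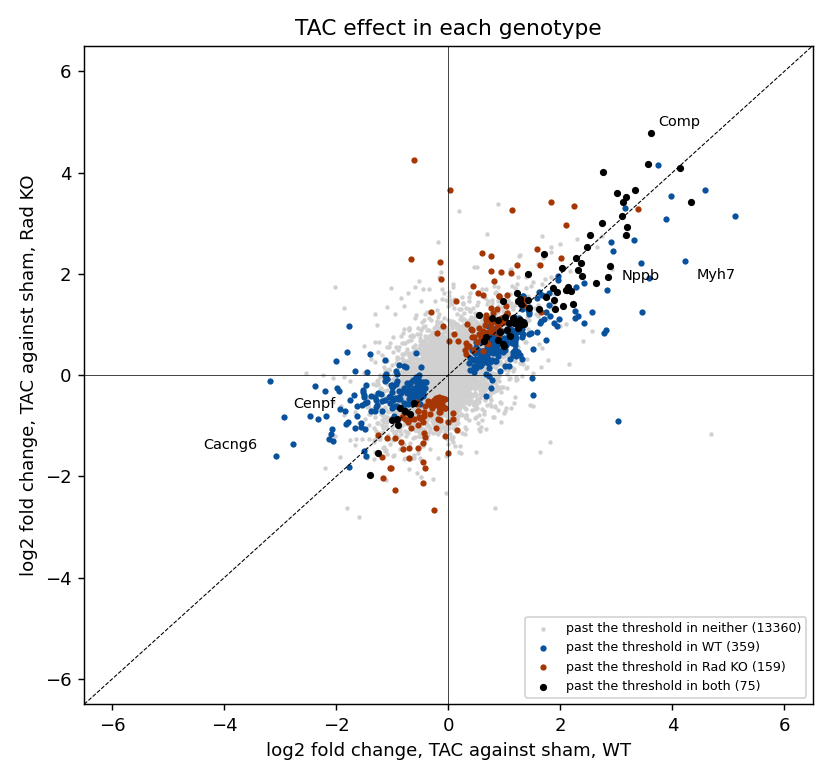
Each point is a gene tested under both labels, with its log2 fold change of TAC against sham in WT on the x axis and in the libraries labelled Rad KO on the y axis; the dashed line marks equal change. Of 13953 genes, 359 passed the threshold in WT alone, 159 in Rad KO alone and 75 in both, and 3 genes lie outside the axes.

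The third comparison asks whether the TAC effect differed between the labels, as the TAC effect in libraries labelled Rad KO minus that in WT. The load-responsive cardiomyocyte genes had differences below 0 for 12 of 12 genes, a smaller TAC effect in the libraries labelled Rad KO, with a median of -0.70 (SE 0.18; limma camera adjusted p = 0.000122, and adjusted p = 0.578 with an estimated correlation). The median was -0.31 (SE 0.17) without WT TAC 3 and -0.35 (SE 0.41) without WT sham 2 and 3 and Rad KO sham 2. It grew to -1.01 without Rad KO TAC 2, -0.85 without WT TAC 4 and -0.82 without WT TAC 1. With each library left out in turn it lay between -1.01 and -0.31, and limma camera with the preset correlation kept the call. Myh7 had a difference of -1.97 (SE 0.76), Nppb of -0.74 (SE 0.61), Xirp2 of -0.86 (SE 0.38) and Ankrd1 of -0.43 (SE 0.54). The Myh7 difference was -1.27 without WT TAC 3 and -1.17 without Rad KO sham 1, and that of Nppb was -0.34 without WT TAC 3 and -0.42 without Rad KO sham 3. Without Rad KO TAC 2, Myh7 had -2.40 and Nppb -1.08. The Ankrd1 difference was -0.19 without WT sham 3, -0.22 without WT TAC 3, -0.19 without Rad KO sham 2, and -0.95, -0.26 and -0.23 without Rad KO TAC 2, 3 and 4. The 15 cell cycle genes had a median difference of 1.06, with 15 of 15 above 0. Set against WT directly, the libraries labelled Rad KO had a list median of -0.60 in sham and 0.23 after TAC. The labels thus differed more in sham than after TAC. Aurkb, a mitotic kinase, had a difference of TAC effects of 2.51, at 0.943 and 0.377 CPM in WT sham and TAC and 0.304 and 0.699 CPM in Rad KO sham and TAC. Of 14731 genes, 0 passed edgeR's quasi-likelihood test, 754 had an unadjusted p under 0.05 where 737 would by chance, and DESeq2 called 8. Members of the lists that follow therefore carry values and no call of their own.

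By limma camera with the preset correlation, 8 lists differed between the labels, 0 did with an estimated correlation, and 0 did by limma fry (lowest adjusted p = 0.252). For TAC in WT and in Rad KO, fry called 4 and 2 lists where camera called 12 and 14, and for Rad KO against WT in sham and TAC 0 and 0 where camera called 5 and 6. With an estimated correlation, camera called 0 lists in each of these comparisons. The lists that fry called for TAC in WT were Schwann cell markers (limma fry adjusted p = 0.00376), load-responsive, TGF-beta and CCN, and potassium, sodium and gap junction channel genes (0.0324 each). In Rad KO they were the same channel list and the cell cycle list (0.046 each). The matrix list was not called by fry (0.0889 in WT and 0.0605 in Rad KO). The cell cycle list had limma camera adjusted p = 8.66e-08, with adjusted p = 0.289 with an estimated correlation, and 1 member, Aurkb, passed when adjusted over the list alone. The interferon-stimulated list had a median of 0.71 (limma camera adjusted p = 1.77e-05, and adjusted p = 0.578 with an estimated correlation), with Usp18, a peptidase of that pathway, at 1.02. Its median was 0.47 without WT sham 2 and 0.41 without Rad KO TAC 1. The fatty acid oxidation list had a median of -0.24 (limma camera adjusted p = 0.00103, and adjusted p = 0.621 with an estimated correlation), with Ucp3 at -1.54. It lost its limma camera call without WT TAC 4 (-0.17, adjusted p = 0.0554), Rad KO sham 2 (-0.13, 0.0756), or WT sham 2 and 3 and Rad KO sham 2 (-0.03, 0.982). The mitochondrially encoded list had a median of -0.30 (limma camera adjusted p = 0.000775, and adjusted p = 0.578 with an estimated correlation), beside mitochondrial shares of 25.6% in Rad KO sham and 21.7% in WT sham. That median was -0.50 without WT sham 1, -0.19 without WT sham 2 and -0.20 without WT TAC 1. The call was lost without Rad KO sham 1 (-0.09, limma camera adjusted p = 0.0716) and without WT sham 2 and 3 and Rad KO sham 2 (-0.15, 0.414).

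The sarcomere, TGF-beta and CCN, and endothelial lists had medians of -0.15, -0.17 and -0.12 (limma camera adjusted p = 0.029, 0.0137 and 0.0312, and adjusted p = 0.613 for each with an estimated correlation). The sarcomere list lost its call without WT sham 2 (-0.09) or 3 (-0.12), WT TAC 1 (-0.12) or 4 (-0.17), Rad KO sham 2 (-0.08), or Rad KO TAC 1 (-0.11) or 3 (-0.10), and its median turned to 0.03 without WT sham 2 and 3 and Rad KO sham 2. The TGF-beta and CCN list lost its call without WT sham 1 (-0.01), WT TAC 3 (-0.03), Rad KO sham 3 (-0.07), or Rad KO TAC 3 (-0.10) or 4 (0.00). It kept the call with -0.32 without WT sham 2 or WT TAC 4, -0.04 without WT TAC 2, -0.26 and -0.09 without Rad KO sham 1 and 2, and -0.37 and -0.28 without Rad KO TAC 1 and 2. The endothelial list lost its call without WT sham 1 (-0.11), WT TAC 1 (-0.12), Rad KO sham 2 (-0.09) or 3 (-0.11), Rad KO TAC 2 (-0.03), or WT sham 2 and 3 and Rad KO sham 2 (-0.15), and had -0.22 without Rad KO TAC 1. Gdf15, a stress cytokine of the TGF-beta family, had a difference of -2.21, from rises of 3.46 in WT and 1.25 in the libraries labelled Rad KO, where the latter did not pass. The growth factor gene Bmp4 had -0.88, and passed when adjusted over the list alone (1 gene). The remaining lists did not pass. Among them, epicardial and mesothelial markers had a median difference of 1.13, with 6 of 6 above 0, and adipocyte markers -1.13, with 3 of 3 below 0 (limma camera adjusted p = 0.0553 for both). Schwann cell markers had 0.82 (limma camera adjusted p = 0.378). Matrix genes had a median difference of 0.11 (limma camera adjusted p = 0.763) and potassium, sodium and gap junction channel genes 0.02 (limma camera adjusted p = 0.245).

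The genes with the smallest p for this difference did not pass. They were Pim1, a serine/threonine kinase, at -0.83 (SE 0.15), the predicted gene Gm33543 at 1.74 (SE 0.33), Irf2bp2, a transcriptional corepressor, at 1.03 (SE 0.20) and Pdzrn4, a PDZ and RING domain gene, at 2.25 (SE 0.46), with an edgeR quasi-likelihood adjusted p of 0.503 for each. On simulated counts for this contrast, with 14521 genes tested, 44.4% of genes changed 2-fold and 76.8% of those changed 4-fold were recovered. The simulated genes were independent and no simulated library stood apart as some real ones did, so recovery in the real data may be lower. Without WT sham 1, edgeR called 4 genes, named here after their values were seen: Ucp2, an uncoupling protein (2.40), Ostn, the osteocrin gene (5.55), Fam81a (2.13) and Gm33543 (1.98).

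**Figure D4:**
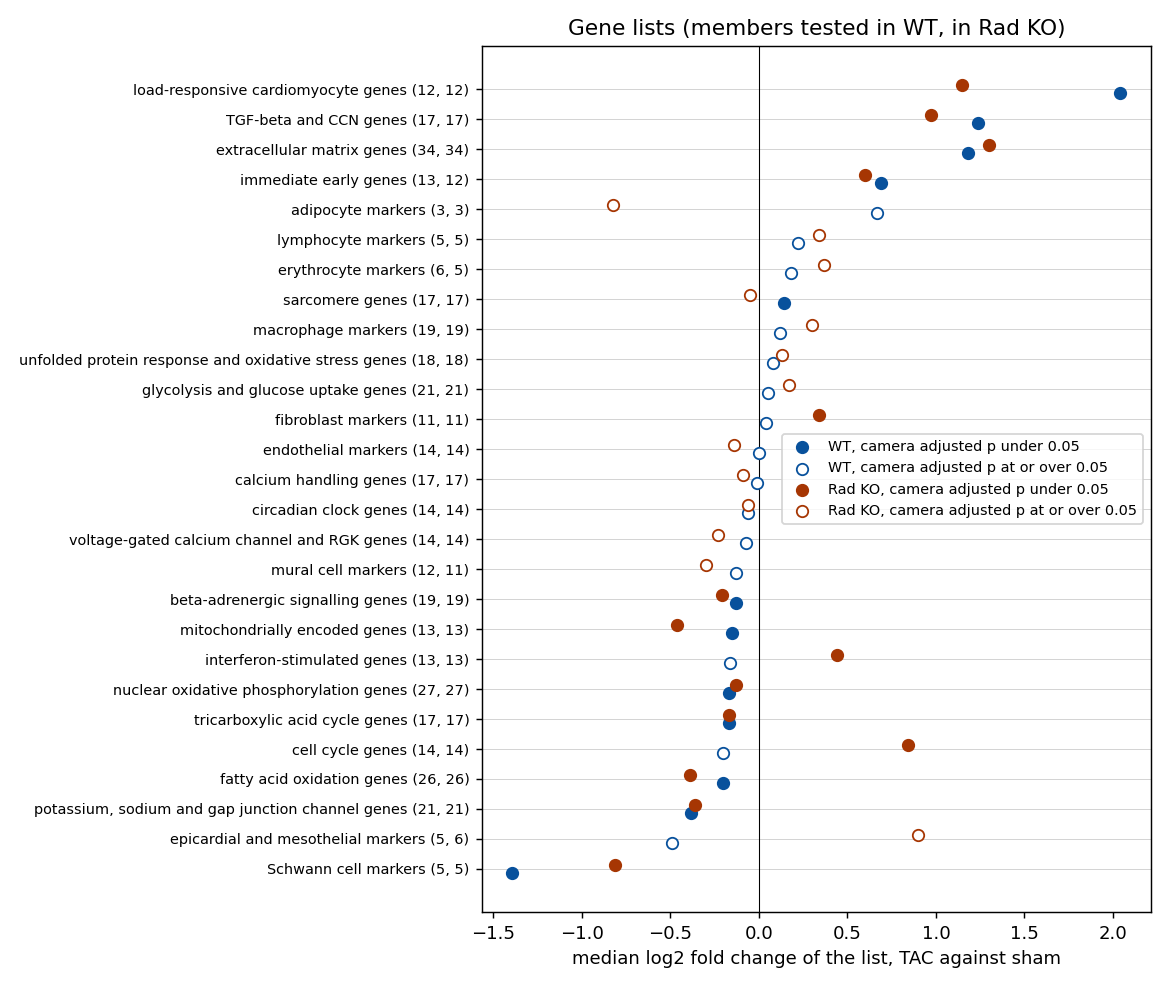
Each point is the median log2 fold change of TAC against sham over the tested members of a gene list, in WT (blue) and in the libraries labelled Rad KO (brown), with the members tested in brackets; filled points had a limma camera adjusted p under 0.05 with the preset correlation of 0.01. The load-responsive list stood at 2.04 in WT and 1.15 in Rad KO, and the extracellular matrix list at 1.18 and 1.30.

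The fourth comparison sets the libraries labelled Rad KO against WT without pressure load. Mitochondrially encoded genes had a list median of 0.36 and cell cycle genes one of -0.60 in Rad KO sham against WT sham. mt-Atp6 had 2053 ± 366 CPM in Rad KO sham and 890.2 ± 175.5 CPM in WT sham (n = 3 each), a log2 difference of 1.21 (SE 0.19, edgeR quasi-likelihood adjusted p = 0.15). The zinc-finger gene Zfp30 had 0.76 (SE 0.14), Gm11361 had -4.72 (SE 0.95) and the ribosomal pseudogene Rpl21-ps15, which may share reads with its parent gene, had -0.68 (SE 0.14). These did not pass (edgeR quasi-likelihood adjusted p = 0.457, 0.523 and 0.523). Of 14731 genes, 0 passed edgeR's quasi-likelihood test, 847 had an unadjusted p under 0.05 where 737 would by chance, and DESeq2 called 17. The limma camera adjusted p were 1.54e-08 for the mitochondrially encoded list and 6.46e-07 for the cell cycle list, with adjusted p = 0.238 for both with an estimated correlation. Fatty acid oxidation genes had a median of 0.21 (limma camera adjusted p = 8.75e-05), extracellular matrix genes -0.30 (0.000657) and interferon-stimulated genes -0.34 (0.000565), with adjusted p = 0.941 for each with an estimated correlation. Members that passed when adjusted over the list alone numbered 1 for the mitochondrially encoded list and 0 for the other 4. The mitochondrial share of counts was 25.6% ± 2.4 in Rad KO sham and 21.7% ± 1.4 in WT sham.

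The fifth comparison sets the same labels against each other after TAC. Pim1 (ENSMUSG00000024014, chromosome 17, 29490812 to 29496111) was lower in Rad KO TAC, at 11.05 ± 0.783 CPM against 17.75 ± 0.575 CPM in WT TAC (n = 4 each), a log2 difference of -0.68 (SE 0.10). Gm33543 (ENSMUSG00000110353, chromosome 10, 95823973 to 95842930) was higher, at 7.05 ± 0.505 CPM against 1.76 ± 0.321 CPM, a difference of 2.00 (SE 0.23). By edgeR's quasi-likelihood test their adjusted p were 0.0234 and 0.0027, and these were the 2 calls among 14731 genes, beside 1143 with an unadjusted p under 0.05 and 96 calls by DESeq2. Esr1, named after its values were seen, had a difference of 10.25 (SE 2.02, edgeR quasi-likelihood adjusted p = 0.0953). All 4 WT TAC libraries had low Esr1 and all 4 Rad KO TAC libraries had high Esr1. Differences in this comparison, for genes and lists alike, therefore cannot be parted from the Esr1 level. Gm33543 was lowest in the low-Esr1 sham library of each label, WT sham 1 (3.72 CPM) and Rad KO sham 2 (5.01 CPM). It had 6.92 and 6.27 CPM in WT sham 2 and 3 and 6.75 and 8.34 CPM in Rad KO sham 1 and 3. Pim1 was highest in those low-Esr1 sham libraries, at 18.32 and 19.96 CPM. The load-responsive list had a median of -0.67 with 12 of 12 members below 0 (limma camera adjusted p = 1.66e-05, and adjusted p = 0.628 with an estimated correlation): Nppb averaged 651 CPM in WT TAC and 370 CPM in Rad KO TAC, and Myh7 3197 and 1269 CPM. Without WT TAC 3, which had 6904 CPM, Myh7 averaged 1961 CPM in WT TAC. Extracellular matrix genes had a median of -0.34 (limma camera adjusted p = 3.41e-05, and adjusted p = 0.715 with an estimated correlation). TGF-beta and CCN genes had -0.18 and voltage-gated calcium channel and RGK genes -0.20 (limma camera adjusted p = 0.000468 and 0.0239, and adjusted p = 0.628 for both with an estimated correlation), and sarcomere genes -0.09 and Schwann cell markers 0.93 (0.00962 and 0.0239, and adjusted p = 0.684 for both). Cell cycle genes (0.23), interferon-stimulated genes (0.20), mitochondrially encoded genes (0.09) and fatty acid oxidation genes (-0.05) were not called after TAC. Their limma camera adjusted p were 0.0827, 0.0627, 0.25 and 0.804. When adjusted over the list alone, 0 load-responsive, matrix and sarcomere genes passed, 1 TGF-beta and CCN gene and 2 calcium channel and RGK genes were lower, and 1 Schwann cell marker was higher. Pim1 lost its call without WT TAC 2 or 3 or Rad KO TAC 2, 3 or 4, with edgeR quasi-likelihood adjusted p between 0.0396 and 0.123 over the 8 libraries left out in turn. The count was 7 without WT TAC 1, 9 without Rad KO TAC 1, and 1 without each of those 5 libraries, where Gm33543 was the call.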

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

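The tests of Esr1 within WT sham, of A1cf, of the region around Mndal and of Mndal in TAC libraries, and the splits of the labels for the 3 contrasts between labels, were chosen only after the result was seen.

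Esr1 parted libraries of the same label. It stood above 338 CPM in 8 libraries and at 1.61 CPM or less in 6, and within WT sham the highest library was 1755 times the lowest, which argues against regulation by the operation or the knockout as the cause. A1cf had 5 to 230 counts in the 8 libraries with high Esr1 and 0 in the other 6, so the 2 went together in 14 of 14 libraries, and a candidate explanation is a transgene holding part of Esr1, such as an inducible Cre, placed beside A1cf. A swap of Rad KO sham 2 with WT sham 2 or 3 was tested on 6 genes that part Rad KO sham 1 and 3 from WT sham 1. Rad KO sham 2 was nearer to its own label on 6 of them, WT sham 2 on 5 and WT sham 3 on 3, so a swap stays open with so few genes. Rrad does not settle it, since its difference between the labels did not pass the threshold.

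Mndal and Ifi205 lie near each other on chromosome 1 and were lower in Rad KO TAC than in Rad KO sham. Of 82 genes tested within 5 Mb of Mndal, 6 were called in Rad KO, 5 of them lower, against 233 of 14040 elsewhere (one-sided Fisher exact p = 0.00265), and a segment from another strain carried by some mice may account for this. Mndal stood at 6.46 CPM in WT TAC 4, below the 8.46 CPM of the lowest Rad KO sham library and above the at most 0.365 CPM of the other TAC libraries. A single library of the other label excludes nothing for Rad KO, so a response to the operation stays open as well. Strain variants were not read here, so the segment stays a hypothesis found and tested on the same data.

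The load-responsive list had a median difference of TAC effects of -0.70 (SE 0.18), and of -1.01 without Rad KO TAC 2. Without WT TAC 3, the library with the highest Myh7, it was -0.31 (SE 0.17), and without WT sham 2 and 3 and Rad KO sham 2 it was -0.35 (SE 0.41). Both values lie below the -0.2 set in advance as the bound against these libraries as the cause, and limma camera with the preset correlation still called the list (adjusted p = 0.0076 and 0.00555, and adjusted p = 0.53 and 0.773 with an estimated correlation). They pass that bound by less than their SE, a condition added to the verdict after the values were seen, so both explanations stay open. That SE takes the 12 genes of the list as independent, where their estimated correlation was 0.51. It does not measure the spread between libraries. A biological effect of the knockout on the load response also stays open and untested, since the labels could not be checked on Rrad.

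By limma camera with the preset correlation, 7 other lists differed in their TAC effect between the labels, with medians of -0.15 for sarcomere genes, -0.17 for TGF-beta and CCN genes, -0.24 for fatty acid oxidation genes, 1.06 for cell cycle genes, 0.71 for interferon-stimulated genes, -0.12 for endothelial markers and -0.30 for mitochondrially encoded genes. With an estimated correlation 0 of these lists passed.

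In 30 of 375 groups of 4 libraries for a named gene, 1 library stood apart (29 of them are listed here), its gap over the group's range exceeding 0.829, where chance gives about 1 in 20. Rad KO TAC 2 stood apart for 9 genes: Adra1a (0.917), Cacnb1 (0.832), Kcnj11 (0.899), Krt19 (0.846), Lgals3 (0.874), Nppa (0.905), Nppb (0.843), Srxn1 (0.947) and Tbx15 (0.954). Nppa was 1350 CPM there against 148 to 262 in the others, and Nppb 605 against 261.5 to 315.5. Rad KO TAC 1 stood apart for Cacna1c (0.854), Cd79b (0.851), Oasl2 (0.837), Pdzrn4 (0.863) and S100a9 (0.834), Rad KO TAC 3 for Hba-a2 (0.853) and Ucp3 (0.903), and Rad KO TAC 4 for Uqcrc1 (0.892) and Zfp30 (0.929). WT TAC 1 stood apart for Cacna2d1 (0.867), Flt1 (0.882), Hba-a2 (0.946) and Ryr2 (0.835), and WT TAC 2 for Muc16 (0.996). WT TAC 3 stood apart for Lgals3 (0.874), Tek (0.901) and Vgll2 (0.871), and WT TAC 4 for Ifi205 (0.854), Mndal (0.974) and Sdhc (0.88).

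Other splits of the libraries were fitted with edgeR in the same way. For TAC in WT, 1 of 35 splits, the real one, gave as many genes as 442, and the highest other gave 46, which argues against a chance split. A smaller share cannot be reached with 35 splits. The splits also do not part TAC from Esr1, which was high in WT sham 2 and 3 and low in every WT TAC library. For TAC in Rad KO, 2 of 35 splits gave as many as the real one, and chance is not excluded: the real split gave 239, and Rad KO TAC 1, 2 and 3 against the rest gave 251. That other split differs from the real one in Rad KO TAC 4 alone. It holds much of the same contrast and does not show where that library belongs. For Rad KO against WT in TAC, 5 of 35 splits gave as many as the real one (real 2, highest other 36), so chance is not excluded. For the difference of the TAC effects (real 0, highest other 11) and for Rad KO against WT in sham (real 0, highest other 0), 100 of 100 and 10 of 10 splits gave as many, as they must where the real count is 0, so these splits say nothing about chance. The 10 splits of the sham libraries are also too few for a share under 0.05.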

How the results depend on the processing

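The tests without sham libraries of unlike Esr1 were chosen only after the result was seen. Rrad stayed short of the threshold in each comparison under every alternative run. For the 2 TAC effects, leaving out 1 library moved the counts of called genes more than the scaling did. With DESeq2 size factors edgeR called 439, 241, 0, 0 and 2 genes for TAC in WT, TAC in Rad KO, their difference, and Rad KO against WT in sham and TAC, and 437 of 442, 239 of 239 and 2 of 2 calls were kept. The replicate numbers were not shown to pair the samples: correlations of equal numbers were 0.06, 0.14 and -0.03 in WT and 0.02, 0.04 and 0.08 in Rad KO. WT sham 1 and 2 and Rad KO sham 3 correlated best with the TAC library of their own number, and WT sham 3 and Rad KO sham 1 and 2 did not. So few samples cannot exclude a pairing.

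In the same order of comparisons, DESeq2 called 933, 753, 8, 17 and 96 genes, and no filter on low counts gave 782, 571, 0, 0 and 21. DESeq2 kept 442 of 442, 239 of 239 and 2 of 2 calls, and no filter kept 438, 239 and 2. The replicate block gave 540, 431, 0, 0 and 1, the 1 being Gm33543, and kept 322 of 442 and 198 of 239 calls of the 2 TAC effects. The cause was not tested for these. An absolute log2 fold change of at least 1 left 236, 137, 0, 0 and 1, and an adjusted p under 0.01 left 59, 16, 0, 0 and 1, by construction. The counts of 0 by edgeR for the difference and in sham came with 1198 and 1086 genes at an unadjusted p under 0.05 without the filter and 789 and 885 with the block. A single model of 14 libraries gave 560 and 207 for the 2 TAC effects and kept 381 of 442 and 155 of 239 calls.

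Leaving out each library in turn, the counts ranged from 15 (without WT sham 3) to 614 (without WT TAC 1) for TAC in WT, 9 (without Rad KO sham 2) to 536 (without Rad KO TAC 4) in Rad KO, 0 to 4 (without WT sham 1) for the difference, 0 to 0 in sham and 1 to 9 (without Rad KO TAC 1) in TAC. Lists called by limma camera ranged from 9 to 13, 12 to 17 and 6 to 10 for the first 3 comparisons, and with an estimated correlation 12, 14 and 8 became 0, 0 and 0. Without WT sham 2 and 3, with fewer samples, edgeR called 0 genes for TAC in WT (947 at an unadjusted p under 0.05), and the lone sham library is assumed to vary like the other group. Without these and Rad KO sham 2, sham had 2 calls, Esr1 (the gene these libraries were chosen by) and Lipo2, TAC had 16, and the sarcomere list's difference reversed to 0.0292 (adjusted p = 0.668). The correlation of the TAC effects moved from 0.57 to 0.74 over called genes and 0.21 without the filter. Of the other alternatives, 2472 results for genes were the same, 135 stronger and 293 weaker, and 979, 44 and 83 for lists.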

Other observations

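The genes of this paragraph were chosen only after their values were seen, and no further tests were run on them. They are single genes from the 75 called for TAC under both labels, and they were not tested as a group. Scx, a tendon transcription factor, rose by 1.75 (SE 0.30) in WT and 1.54 (SE 0.29) in the libraries labelled Rad KO, and Col9a2, a cartilage collagen, by 2.86 (SE 0.63) and 1.94 (SE 0.42). Mybpc2, the fast myosin-binding protein, rose by 2.10 (SE 0.25) and 1.67 (SE 0.27), Myot, a Z-disc protein, by 2.19 (SE 0.24) and 1.66 (SE 0.22), Ankrd23, a titin-binding repeat protein, by 1.94 (SE 0.27) and 1.64 (SE 0.24), and the growth factor gene Fgf6 by 2.63 (SE 0.43) and 1.81 (SE 0.36). Tnfrsf12a, the TWEAK receptor, rose by 2.12 (SE 0.30) and 1.68 (SE 0.33), the hyaluronan receptor gene Cd44 by 0.98 (SE 0.22) and 1.46 (SE 0.28), the endothelin gene Edn3 by 1.87 (SE 0.37) and 1.72 (SE 0.19), and Dkk3, of a family of Wnt regulators, by 1.70 (SE 0.38) and 2.39 (SE 0.35). Gpr22, a cardiac orphan receptor, had -0.77 (SE 0.17) and -0.71 (SE 0.13), Rnf207, a ubiquitin ligase gene, -0.61 (SE 0.12) and -0.56 (SE 0.11), and the synaptotagmin gene Syt7 -0.86 (SE 0.20) and -0.65 (SE 0.12). By edgeR's quasi-likelihood test their adjusted p lay between 0.00456 for Myot in WT and 0.0498 for Syt7 in WT.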
